A study of Mus musculus with 6 samples.

How the data were processed

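RNA was sequenced from LSK cells of 6 mouse marrow samples, 3 labelled vector and 3 labelled Hmga2, with group and replicate taken from the sample titles. The values deposited by the authors were expected counts, that is estimated counts per gene symbol, 1 column per library, judged from the values themselves: none was negative, between 67.3% and 70.1% of the values above 0 were whole within 1e-06, and column totals differed. Per the submitters' processing notes the tools were Partek 3.0 and Bowtie2 and the genome build was mm10; the counter, the annotation and the strand setting are not given in the sources used here. Estimated counts assign reads shared between similar genes by a model, so values of near-identical genes, such as Mt1 and Mt2, immunoglobulin segments, the H2, Gbp and Irgm families and pseudogene copies, are uncertain, as are genes that overlap an antisense partner.

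The tables held 48395 symbols, of which 26164 had a value above 0 in at least 1 library. Rows of mitochondrially encoded genes were listed at 0 in every library, while 5 mitochondrial pseudogenes of the nuclear genome took 1.48% to 2.04% of counts, so the mitochondrial share could not be used as a measure of RNA quality. In 27 rows the symbol had been turned into a date, and 2 of these date symbols occurred more than once; no list used them. Replicates were compared before averaging, and each pair within a group differed by more than sampling noise (chi-square per degree of freedom from 24.8 to 57).

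Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM normalization, quasi-likelihood fit and F test on group alone, and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes are log2 of labelled Hmga2 over vector, and their standard errors were taken from the F statistic. CPM values of single genes were scaled by TMM factors, while immunoglobulin shares, summed Y-linked genes and Xist per library refer to the total of each library. At total counts of 24818011 to 35471806 per library, 3 reads correspond to 0.0846 to 0.121 CPM, a floor for counting error only; intervals of fold changes cover the spread between these libraries. DESeq2 1.42.0 was the other tool. Of 29 gene lists fixed in advance, 28 had at least 5 measured members and were tested with camera and fry of limma 3.58.1 on log2 CPM with a prior count of 2; the mitochondrial list was not tested for the reason above.

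Named genes followed a rule: Hmga2, Jak2, Tgfb1, Cxcl12 and Cxcr4 in any case; up to 12 genes in each direction past the threshold; and, as fewer than 5 qualified, the 10 genes with the smallest unadjusted p-values among those whose groups did not overlap and whose higher group had a mean of at least 5 CPM, without unnamed, predicted or immunoglobulin genes. Up to 4 members with the smallest p-values could be named in each described list. Some genes that this rule takes are not reported here. Igf2bp2, Mobp, Elane, Ly6a, Hbb-bs, Hba-a1, Igha, Xist, Txnip, Tgfbr3 and the genes named only in the closing section fall outside this rule and were chosen after their values were seen. The tests, samples, gene lists, naming rule and first set of alternatives were fixed before the data were examined. Those alternatives were a replicate block, each library left out in turn, other size factors, no count filter, DESeq2, a 2-fold minimum, an estimated correlation and fry; a robust fit, leaving out immunoglobulin genes and terms for immunoglobulin-rich libraries (Igha above 1000 CPM) and for Y-linked genes were added after seeing the data.

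The steps were tested on simulated counts for the same 16739 genes and library sizes with 200 changed genes. At 2-fold, edgeR recovered 38 of 100 changed genes and DESeq2 59; at 4-fold, edgeR recovered 69 of 100 and DESeq2 79; false calls numbered 7 for edgeR and 40 for DESeq2, and no changed gene was called in the wrong direction. A simulated list was called by camera with either correlation and 0 other lists were, but the simulated genes were independent of each other. Positions come from GENCODE M21, annotated on the same build as the authors' mm10, where 97.3% of tested symbols were found.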

Results

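Gene expression was measured by RNA sequencing in LSK cells sorted from mouse bone marrow, the lineage-negative, Sca-1-positive and c-Kit-positive fraction that holds haematopoietic stem cells and early progenitors. The marrow carried an activating allele of Jak2, the kinase that relays signals from the erythropoietin and thrombopoietin receptors, and had been transduced with lentivirus before transplantation into irradiated recipients. Of the 6 libraries, 3 were labelled vector (the vector libraries) and 3 were labelled Hmga2, and each came from marrow collected 32 weeks after transplantation. The labels describe the libraries of a group as biological replicates. Total counts per library ranged from 24818011 to 35471806, and 16739 genes passed the count filter. The comparison addressed how added Hmga2, a chromatin protein that binds AT-rich DNA, altered expression in Jak2-mutant LSK cells.

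Hmga2 itself was no higher in the libraries labelled Hmga2. The gene (chromosome 10, positions 120361275 to 120476469 on mm10) was measured at 5.96, 5.04 and 7.03 CPM in the vector libraries and at 2.63, 6.63 and 5.91 CPM in the libraries labelled Hmga2. The log2 fold change, labelled Hmga2 minus vector, was -0.25 with a standard error of 0.35 and a 95% interval from -1.08 to 0.58 (adjusted p = 0.934, edgeR). An exact two-sided permutation test of the 6 values gave p = 0.6, where the smallest value this design allows is 0.1. Between 93 and 204 reads per library lay behind these values, and the upper bound corresponds to a 1.5-fold rise. Whether reads of the introduced sequence were counted for this gene is not given in the sources used here. The log2 fold change was 0.06 without Hmga2 replicate 1 and 0.12 with a term for Y-linked genes. Igf2bp2, which encodes an RNA-binding protein and is a known Hmga2 target gene, had a log2 fold change of 0.39 with a standard error of 0.33. Since the label was not borne out by the gene it names, directions below are given for the libraries labelled Hmga2 and are not directions of an Hmga2 effect.

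Metallothionein transcripts were lower in the libraries labelled Hmga2, although no gene passed the adjusted threshold in edgeR with the count filter and group alone. Mt1, which encodes a zinc- and copper-binding protein, was at 89.6 ± 9.37 CPM in the vector libraries and at 38.5 ± 3.34 CPM in the libraries labelled Hmga2 (SD, n = 3 each), a log2 fold change of -1.22 with a standard error of 0.11 (adjusted p = 0.156). Its neighbour and close paralog Mt2 was at 41.8 ± 9.99 and 14.9 ± 2.96 CPM. Ccne1, encoding cyclin E1 of the G1 to S transition, was at 39.4 ± 4.35 and 23.2 ± 1.13 CPM. The haem-binding protein gene Hebp1 was at 17 ± 1.47 and 9.64 ± 0.695 CPM. Crip2, Epdr1 and Fam101b were also lower, with log2 fold changes of -1.44, -0.84 and -1.35. Nmral1, which encodes a redox-sensing protein, was higher, at 55.7 ± 4.73 and 89.7 ± 10.9 CPM. Gfap, an intermediate filament gene of astrocytes, was at 11.6, 9.57 and 3.77 CPM in the vector libraries and at 1.24, 1.56 and 0.728 CPM in the libraries labelled Hmga2. Mobp, a myelin gene, was at 38.7, 46.7 and 4.98 CPM and at 0.876, 4.68 and 0.758 CPM. Apart from Mobp, these genes were among the 10 with the smallest unadjusted p-values of expressed genes whose groups did not overlap, and apart from Mt1 their adjusted p was 0.855 in edgeR. DESeq2 called all of them except Mobp, with adjusted p = 8.46e-17 for Mt1 and adjusted p = 3.06e-08 for Mt2. Of 18 neural genes not examined before, 13 were lower and 5 higher, with a median of -0.22 (adjusted p = 0.00501 with the preset correlation described below; adjusted p = 0.198 with an estimated correlation).

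The quasi-likelihood test of edgeR called 0 of the 16739 genes, and 935 genes had an unadjusted p under 0.05, of which 373 were higher and 562 lower in the libraries labelled Hmga2; chance alone gives 837. The groups did not overlap for 1868 genes, or 11.2%, against the 10% that chance gives for 3 libraries against 3. DESeq2 called 67 genes from the same counts, 8 higher and 59 lower, among them Mt1, Mt2, Ccne1, Gfap and Cxcl12. On simulated counts for the same genes, with 200 genes changed, DESeq2 made 40 false calls beside 59 true calls at 2-fold and 79 at 4-fold. With edgeR, 7 false calls stood beside 38 and 69 true ones. How many genes truly differ here is unknown, so 40 is no estimate of the false calls among the 67. Without the filter on low counts edgeR called 1 gene, Mt1 (adjusted p = 0.0446).

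**Figure D1:**
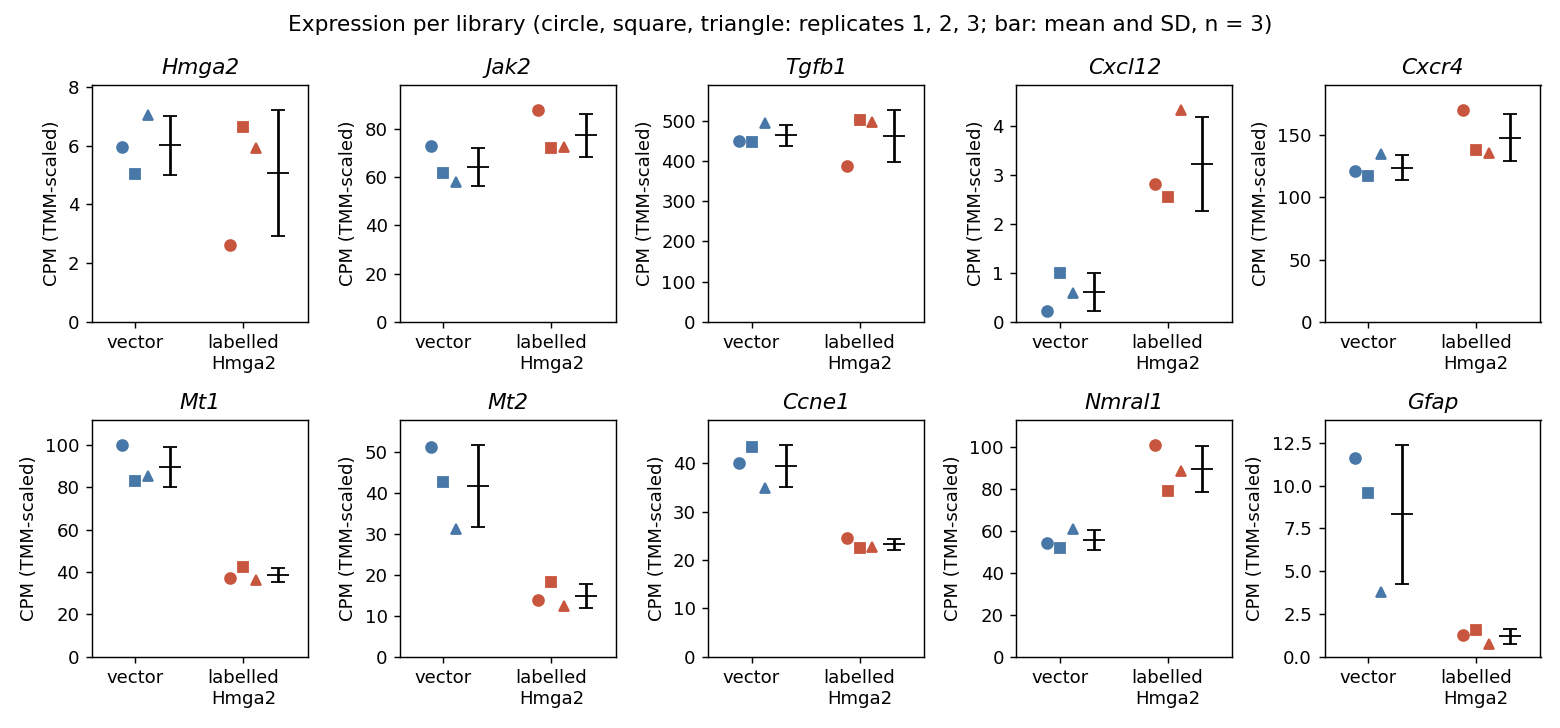
Expression of 10 named genes in CPM scaled by TMM factors (vertical axes, starting at 0) in the 3 vector libraries and the 3 libraries labelled Hmga2; circles, squares and triangles are replicates 1, 2 and 3, and bars give the mean and SD (n = 3). Hmga2 overlapped between the groups, while the Mt1 libraries lay between 83.2 and 100 CPM for vector and between 36 and 42.3 CPM for the libraries labelled Hmga2.

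Among genes chosen in advance for this disease model, Cxcl12, the chemokine that retains stem cells in the marrow, showed the widest difference. It was at 0.602 ± 0.39 CPM in the vector libraries and 3.22 ± 0.959 CPM in the libraries labelled Hmga2 (SD, n = 3 each), with all 3 of the latter above all 3 of the former. The log2 fold change of 2.42 had a standard error of 0.52 and did not pass over all genes in edgeR (adjusted p = 0.855), but passed in DESeq2 (adjusted p = 0.0036). Its receptor gene Cxcr4 was at 124 ± 9.99 and 148 ± 19.1 CPM, and Jak2 at 64.2 ± 7.84 and 77.3 ± 8.96 CPM, with adjusted p = 0.855 for each. Tgfb1, encoding a cytokine that drives marrow fibrosis, was at 463 ± 25.4 and 461 ± 64.4 CPM (adjusted p = 0.999).

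Gene lists fixed in advance were compared with all other genes by camera with a preset correlation of 0.01, which called 12 of 28 lists, 6 higher and 6 lower in the libraries labelled Hmga2. With an estimated correlation camera called 0 lists (smallest adjusted p = 0.45), and fry called 0 (smallest adjusted p = 0.193). The other ways of parting the same 6 libraries into groups of 3 called between 5 and 16 lists with the preset correlation. Over all genes, 0 members of any list passed in edgeR. DESeq2 called 6 members of the erythroid list and 5 of the granulocyte list over all genes, and Cxcl12, Sparc, Odc1 and Bach2 from other lists.

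Both interferon lists were called higher in the libraries labelled Hmga2 with the preset correlation only. Of 38 measured members of the type I interferon list, 33 had a positive log2 fold change, with a median of 0.22 (adjusted p = 7.6e-06; adjusted p = 0.519 with an estimated correlation). Parp14 was at 52.9 ± 1.35 and 67.9 ± 7.87 CPM, Oas3, which senses double-stranded RNA, at 12.1 ± 3.1 and 18.4 ± 2.62 CPM, and Cmpk2 at 15.6 ± 1.35 and 19.8 ± 3.31 CPM (vector, then labelled Hmga2). Of 29 members of the interferon gamma and antigen presentation list, 27 were positive, with a median of 0.30 (adjusted p = 4.45e-06; adjusted p = 0.62 with an estimated correlation). The peptide transporter gene Tap1 was at 289 ± 13 and 340 ± 5.34 CPM, Gbp2 at 40.9 ± 6.56 and 57.7 ± 9.4 CPM, and the class II gene H2-Eb1 at 69.9 ± 12.7 and 131 ± 61.3 CPM. Adjusted over the list alone, 0 members of either list passed. Both calls were kept with each library left out in turn. The type I median was 0.14 without vector replicate 2, and the interferon gamma median was 0.46 without Hmga2 replicate 2, 0.18 without Hmga2 replicate 1 and 0.16 with a term for Y-linked genes. Among immunoglobulin-rich libraries only (Hmga2 replicate 2 against vector replicates 1 and 3), the interferon gamma median was 0.05 and the type I median 0.2. Among the others (Hmga2 replicates 1 and 3 against vector replicate 2), these medians were 0.45 and 0.33.

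Lists of growth, energy and immediate early genes were called lower with the preset correlation only. In the list of MYC targets and ribosome biogenesis, 35 of 36 measured members had a negative log2 fold change, with a median of -0.20 (adjusted p = 3.87e-11; adjusted p = 0.672 with an estimated correlation). Odc1, the first enzyme of polyamine synthesis, was at 285 ± 10.5 and 221 ± 11.8 CPM, and spermidine synthase, Srm, at 277 ± 44.6 and 209 ± 14.8 CPM. In the oxidative phosphorylation list 55 of 56 members were negative, with a median of -0.15 (adjusted p = 5.18e-09, and adjusted p = 0.754 with an estimated correlation). Its members varied together (estimated correlation 0.705), so the 55 are not separate observations. The groups did not overlap for 7 of the 56, beside 11.2% of all genes. In log2 CPM minus each gene's mean, the list median of Hmga2 replicate 2 (0.04) lay above that of vector replicate 1 (-0.09). The complex II subunit gene Sdhd was at 184 ± 13.6 and 157 ± 4.09 CPM. Both calls were kept with each library left out. The oxidative phosphorylation median was -0.25 without vector replicate 1, -0.06 without vector replicate 3 and -0.08 with a term for Y-linked genes, with which the MYC median was -0.31. Eno1, the glycolytic enolase, was at 513 ± 44.2 and 431 ± 27.9 CPM. The glycolysis and hypoxia list had 23 of 30 members negative and a median of -0.11 (adjusted p = 0.0125; adjusted p = 0.672 with an estimated correlation), and this call ended without vector replicate 2 (adjusted p = 0.0576), vector replicate 3 (adjusted p = 0.0902) or Hmga2 replicate 2 (adjusted p = 0.125). Its median was -0.05 without vector replicate 3 and -0.17 without vector replicate 1. Immediate early genes, which respond within minutes to stimulation or cell handling, had 21 of 25 members negative and a median of -0.57 (adjusted p = 0.0291; adjusted p = 0.754 with an estimated correlation). The chaperone gene Hspa1a was at 90.6 ± 44.7 and 43 ± 29.8 CPM. That difference rested on vector replicate 1, without which the median was -0.01 and the test pointed the other way (adjusted p = 0.919). The call also ended without Hmga2 replicate 1 (adjusted p = 0.0695) or replicate 2 (median -0.30, adjusted p = 0.701), and the median was -0.86 without vector replicate 3, -1.08 without Hmga2 replicate 3 and -0.90 with a term for Y-linked genes. Adjusted over the list alone, 0 members of these 4 lists passed, against 5 of the MYC list without vector replicate 1 and 19 with a term for Y-linked genes.

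The erythroid and granulocyte lists were called lower in the libraries labelled Hmga2 with the preset correlation only, and not all members were lower. Of 34 measured erythroid genes 25 had a negative log2 fold change, with a median of -0.47 (adjusted p = 5.18e-09; adjusted p = 0.45 with an estimated correlation), and 6 fell when adjusted over the list alone, against 0 over all genes in edgeR and 6 in DESeq2. The 9 others included the globin genes Hbb-bs, at 200 ± 91.7 and 225 ± 212 CPM, and Hba-a1, at 153 ± 75.8 and 174 ± 165 CPM. The count of 6 was 0 without vector replicate 2 or Hmga2 replicate 3, 1 without Hmga2 replicate 2, 10 without Hmga2 replicate 1 and 16 without vector replicate 3. It was 12 with immunoglobulin genes left out, 14 with a term for immunoglobulin-rich libraries and 4 with a term for Y-linked genes. Of the 6, the blood group gene Rhd was at 26.5 ± 8.88 and 9.58 ± 2.8 CPM and Blvrb, encoding a biliverdin reductase, at 78.6 ± 19.8 and 45.5 ± 7.25 CPM. Of 34 granulocyte genes 28 were negative, with a median of -0.73 (adjusted p = 5.71e-10; adjusted p = 0.457 with an estimated correlation), and 8 fell when adjusted over the list alone, against 0 over all genes in edgeR and 5 in DESeq2. That count was 0 without vector replicate 2, Hmga2 replicate 1 or Hmga2 replicate 3, 2 without vector replicate 3, 4 without vector replicate 1 and 13 with a term for immunoglobulin-rich libraries. Haptoglobin, Hp, was at 67.4 ± 24.8 and 31.6 ± 5.16 CPM, Ms4a3 of granulocyte and monocyte progenitors at 213 ± 67.1 and 104 ± 23.8 CPM, and the granule genes Ltf and Ngp at 2.28 ± 0.186 and 0.254 ± 0.316 CPM and at 3.32 ± 2.29 and 0.443 ± 0.302 CPM. Vector replicate 2 had the highest level of the neutrophil elastase gene Elane, 843 CPM against 348 and 253 CPM in the other vector libraries. It had the lowest level of Ly6a, which encodes the Sca-1 antigen used for sorting, 19.3 CPM against 51.5 and 59.1 CPM. Hmga2 replicates 1, 2 and 3 had Elane at 187, 173 and 149 CPM and Ly6a at 32.2, 45.5 and 33.2 CPM. Ly6a was thus higher in each immunoglobulin-rich library (vector replicates 1 and 3 and Hmga2 replicate 2) than in every other library. Both list calls were kept with each library left out. The granulocyte median was -0.48 without vector replicate 2 and the erythroid median -0.71 without Hmga2 replicate 3.

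The stem cell and megakaryocyte lists were called higher with the preset correlation only, and the stem cell call did not hold with each library left out. The megakaryocyte and platelet list had 28 of 32 measured members with a positive log2 fold change and a median of 0.30 (adjusted p = 7.6e-06; adjusted p = 0.754 with an estimated correlation). The transcription factor gene Fli1 was at 69.9 ± 7.29 and 87.3 ± 4.52 CPM, and the thrombin receptor gene F2r at 152 ± 12.1 and 202 ± 44.9 CPM. The haematopoietic stem cell list had 29 of 39 members positive and a median of 0.18 (adjusted p = 0.0164; adjusted p = 0.754 with an estimated correlation). Runx1 was at 96.9 ± 7.81 and 116 ± 3.28 CPM and Meis1, a homeobox gene of stem cells, at 111 ± 23.3 and 153 ± 19.3 CPM. The megakaryocyte call was kept with each library left out, with a median of 0.52 without vector replicate 1, 0.18 without vector replicate 2, 0.15 without vector replicate 3, 0.17 without Hmga2 replicate 2 and 0.47 with a term for Y-linked genes. Vector replicate 1 had the highest median of the stem cell list among the 6 libraries, 0.60 in log2 CPM minus each gene's mean over the libraries. The stem cell call ended without vector replicate 2, where the median was 0.00 (adjusted p = 0.694), and without vector replicate 3 (median 0.06, adjusted p = 0.21), Hmga2 replicate 2 (median 0.07, adjusted p = 0.211) or Hmga2 replicate 3 (median 0.09, adjusted p = 0.187). Its median was 0.54 without vector replicate 1 and 0.36 with a term for Y-linked genes or for immunoglobulin-rich libraries. Adjusted over the list alone, 0 members of either list passed, against 6 megakaryocyte genes and 1 stem cell gene, Txnip, without vector replicate 1.

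**Figure D2:**
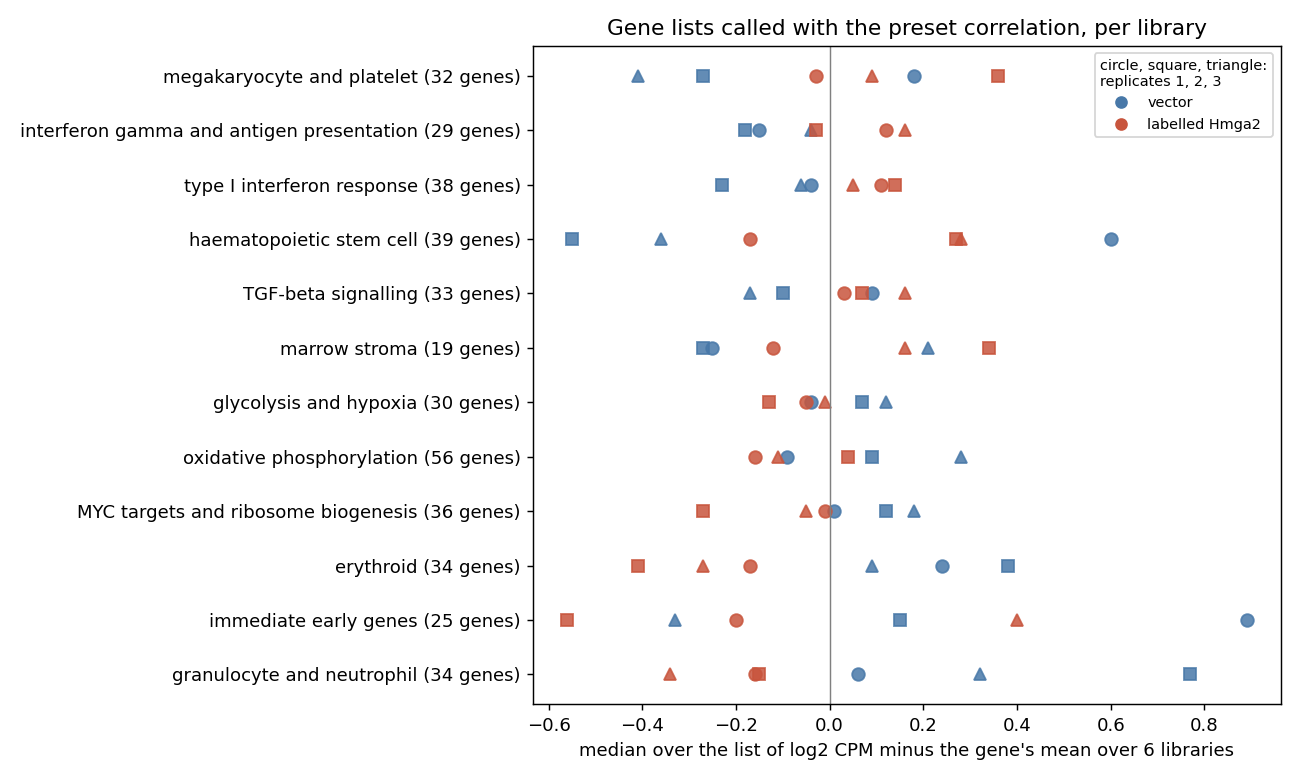
Gene lists called with the preset correlation (vertical axis) and, for each library, the median over the list of log2 CPM minus each gene's mean over the 6 libraries (horizontal axis); blue is vector, red is labelled Hmga2, and circles, squares and triangles are replicates 1, 2 and 3. The groups lay apart for the erythroid list, with vector libraries from 0.09 to 0.38 and libraries labelled Hmga2 from -0.41 to -0.17, and overlapped for the stem cell list.

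Of the signalling and matrix lists, TGF-beta signalling and marrow stroma were called. TGF-beta signalling genes had 21 of 33 measured members with a positive log2 fold change and a median of 0.16 (adjusted p = 0.0323; adjusted p = 0.754 with an estimated correlation). Smad3, a signal transducer of the pathway, was at 57.5 ± 6.28 and 75.3 ± 4.04 CPM and the receptor gene Tgfbr2 at 52.1 ± 0.488 and 64.3 ± 5.83 CPM, while the target gene Id1 was at 4.32 ± 1.11 and 2.37 ± 0.616 CPM. This call ended without vector replicate 2 (adjusted p = 0.0626), vector replicate 3 (adjusted p = 0.105) or Hmga2 replicate 3, where the median was -0.03 (adjusted p = 0.667), and with a term for immunoglobulin-rich libraries (adjusted p = 0.0946) or Y-linked genes (median 0.10, adjusted p = 0.234). The marrow stroma list had 11 of 19 members positive and a median of 0.07 (adjusted p = 0.0499; adjusted p = 0.754 with an estimated correlation). Cxcl12 rose when adjusted over the list alone (adjusted p = 0.0437), though not without vector replicate 3 or any of the 3 libraries labelled Hmga2, nor with a term for Y-linked genes. Without vector replicate 1, 3 members passed in this way. Col1a1, encoding a type I collagen chain, was at 0.475 ± 0.148 and 1.32 ± 0.582 CPM. The stroma call ended without vector replicate 1 (adjusted p = 0.133), vector replicate 2 (adjusted p = 0.346), Hmga2 replicate 2 (adjusted p = 0.259) or Hmga2 replicate 3 (adjusted p = 0.207), and was kept without vector replicate 3 or Hmga2 replicate 1. Its median was 0.14, 0.03 and 0.22 without vector replicates 1, 2 and 3, 0.25, 0.04 and 0.06 without Hmga2 replicates 1, 2 and 3, 0.33 with a term for Y-linked genes and 0.29 with a term for immunoglobulin-rich libraries. The chemokine list, with 16 of 22 members positive and a median of 0.22, was not called (adjusted p = 0.249), except without Hmga2 replicate 2 (adjusted p = 0.00709). Its median was 0.00 without Hmga2 replicate 3, 0.05 with a term for immunoglobulin-rich libraries and -0.06 with a term for Y-linked genes. JAK-STAT genes, 19 of 33 positive with a median of 0.02 but a mean of -0.03 (adjusted p = 0.514), and extracellular matrix genes, 12 of 27 positive with a median of -0.02 (adjusted p = 0.713), were not called. In the matrix list Sparc, a collagen-binding protein also made by glia, fell when adjusted over the list alone (adjusted p = 0.0468), from 9.01 ± 4.3 to 2.01 ± 0.803 CPM, a call lost with each library left out in turn and with either term. Adjusted over the list alone, 0 members of the TGF-beta, chemokine and JAK-STAT lists passed, though Smad3 and Tgfbr3 passed without vector replicate 1. Cxcl12 passed in the chemokine list without vector replicate 1 or 2, with immunoglobulin genes left out and with a term for immunoglobulin-rich libraries. The matrix median turned to 0.13 with a term for Y-linked genes, to 0.13 with a term for immunoglobulin-rich libraries, to 0.04 without vector replicate 1 and to 0.01 without Hmga2 replicate 1.

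Immunoglobulin transcripts varied widely between libraries of both groups. Immunoglobulin genes took 1.85%, 0.0801% and 1.52% of counts in vector replicates 1, 2 and 3 and 0.0886%, 0.642% and 0.0631% in Hmga2 replicates 1, 2 and 3. Igha, the heavy chain gene of IgA, was at 8930, 193 and 5470 CPM in the vector libraries and at 236, 2530 and 214 CPM in the libraries labelled Hmga2. The B cell and plasma cell list was not called (median -0.44, adjusted p = 0.306), except without vector replicate 2, where the median was -0.86 (adjusted p = 0.000115). Its median was -0.19 without vector replicate 3, -0.24 without Hmga2 replicate 1 and -0.16 with a term for immunoglobulin-rich libraries. Of 19 plasma cell genes not examined before, 17 were lower in the libraries labelled Hmga2, with a median of -0.28 (adjusted p = 3.32e-05 with the preset correlation; adjusted p = 0.0547 with an estimated correlation). Adjusted over the B cell and plasma cell list alone, Xbp1, a regulator of secretory cells, fell from 166 ± 4.88 to 131 ± 7.69 CPM and Bach2, a repressor of plasma cell differentiation, rose from 6.86 ± 0.13 to 11.4 ± 1.71 CPM (adjusted p = 0.0401 for each), and neither passed with any 1 library left out or with a term for immunoglobulin-rich libraries or Y-linked genes. The first principal component of the 1000 most variable genes held 52% of the variance and placed vector replicates 1 and 3 and Hmga2 replicate 2 on one side and the other libraries on the other. Summed Y-linked genes were at 191 and 129 CPM in Hmga2 replicates 1 and 3, 21.4 CPM in vector replicate 2 and between 5.24 and 6.73 CPM in the others, and Xist, expressed from the inactive X chromosome of female cells, was at 29.1 and 168 CPM in Hmga2 replicates 1 and 3 and between 449 and 645 CPM in the others. Spearman correlations ranged from 0.971 to 0.987 within groups and from 0.973 to 0.986 between groups.

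**Figure D3:**
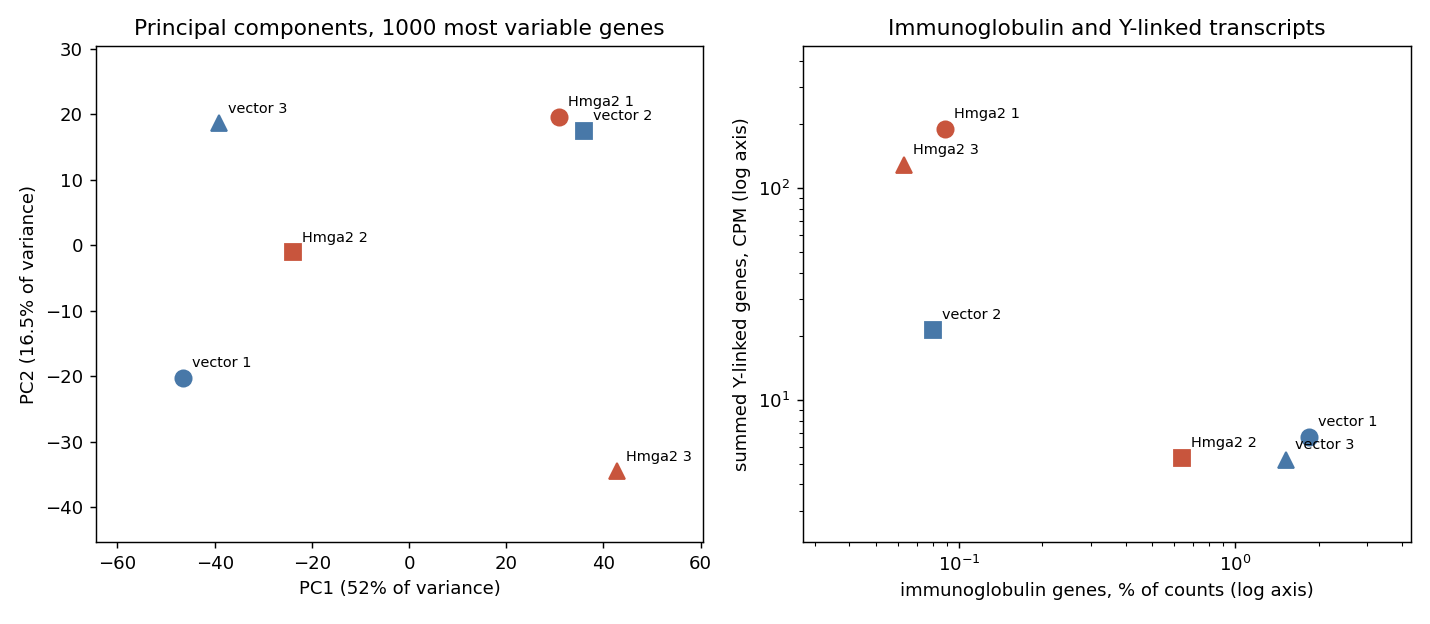
Left, the first and second principal components of log2 CPM of the 1000 most variable genes, with the percentage of variance on each axis. Right, the share of counts in immunoglobulin genes (percent, log axis) against summed Y-linked genes (CPM, log axis); blue is vector, red is labelled Hmga2, 1 point per library, and Hmga2 replicates 1 and 3 stand highest on the vertical axis at 191 and 129 CPM.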

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

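Tests with a robust fit, without immunoglobulin genes and with terms for immunoglobulin-rich libraries or Y-linked genes were chosen only after the results were seen. With edgeR the count of called genes stayed at 0 with the replicate block, other size factors, a robust fit, immunoglobulin genes left out, the immunoglobulin term, a 2-fold minimum and each library left out in turn, and was 1, lower, without the count filter (Mt1) and 1, lower, with the Y-linked term (Ighv1-78); DESeq2 called 67, 8 higher and 59 lower. Same-numbered libraries showed no sign of pairing (correlations of their deviations -0.21, -0.5 and -0.26). They lay on opposite sides of the immunoglobulin split, which can lower these correlations, so a shared donor or day stays open. With the replicate block 0 genes and 12 lists were called and the Hmga2 log2 fold change was -0.34. Members called over the list alone then went from 6 to 12 (erythroid), 0 to 3 (interferon gamma), 8 to 0 (granulocyte), 2 to 0 (B and plasma cell) and 1 to 0 (matrix and stroma). The Hmga2 log2 fold change turned to 0.12 with the Y-linked term and ranged from -0.49 to 0.06 over libraries left out. List calls fell from 12 to 0 with an estimated correlation and to 0 with fry, and numbered 10 to 14 over libraries left out, 8 to 11 of them among the 12; all 12 were kept with other size factors and the replicate block, and with immunoglobulin genes left out, which moved no fold change by over 0.03 and so tests little, though members called over the erythroid list alone went from 6 to 12. With the immunoglobulin term these were 14 (erythroid) and 13 (granulocyte), and with the Y-linked term 4 and 7. Tgfb1 turned to 0.03 with the immunoglobulin term and 0.10 with the Y-linked term (range -0.07 to 0.11 over libraries left out). List medians turned for chemokines (-0.06 with the Y-linked term), TGF-beta (-0.03 without Hmga2 replicate 3) and extracellular matrix (0.13 with either term, 0.02 with the replicate block, -0.12 to 0.04 over libraries left out), and test directions turned for JAK-STAT (-0.02 to 0.10) and immediate early genes (-1.08 to -0.01). The first component held 41.4% of the variance over all filtered genes. Of 1005 other values for 72 genes, 979 kept direction and side of the threshold. None of these genes passed in the edgeR fit on group alone with all libraries, and most were picked there by small p-values. Their count of 979 was therefore largely set beforehand. Of 208 values for 16 lists, 157 kept both. Causes were not tested.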

Other observations

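Tests of the Hmga2 interval, of Igf2bp2 and of the sex-linked genes were chosen only after the results were seen. So were those of normalization without immunoglobulin genes and of splits for gene calls. Predictions for further plasma cell, neural and ATF4 genes and for splits of list calls were written before those values were examined. These gene sets were not among the lists fixed in advance. Other neural and ATF4 genes had already been seen to differ in the same libraries, so tests of the further ones are not independent of them. The limit of 10 CPM and the comparison with other splits for ATF4 targets were added afterwards. Both leave open what the earlier bounds would have decided. Genes of the cell cycle and of several other cell types were not called between the labelled groups, with medians (labelled Hmga2 minus vector) of 0.03 for G2/M (adjusted p = 0.0727), -0.02 for S phase (adjusted p = 0.365), -0.03 for ribosomal proteins (adjusted p = 0.141), 0.01 for NF-kB targets (mean -0.01, adjusted p = 0.713), 0.01 for p53 targets (adjusted p = 0.532) and 0.01 for the Hmga2, let-7 and Lin28 axis (adjusted p = 0.958). Lymphoid-primed progenitor genes had a median of 0.22 (adjusted p = 0.141), monocyte and macrophage genes -0.08 (adjusted p = 0.365), mast cell and basophil genes -0.21 (adjusted p = 0.365), T and NK cell genes 0.16 (adjusted p = 0.0775), endothelial genes 0.25 (adjusted p = 0.141) and the 5 measured sex-linked genes 2.71 (adjusted p = 0.223). These values, from camera with the preset correlation, are for all libraries. Some of these lists were called with a library left out. Without Hmga2 replicate 2, 14 lists were called, 8 of them among the 12. Without vector replicate 1, 13 were called, 10 of them among the 12.

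Splitting the 6 libraries into groups of 3 in all 10 ways gives too few splits for a share under 0.05. The labelled split called 0 genes, a count that all 10 splits reach by construction, so this comparison decides nothing. The highest other split called 37, all higher in vector replicates 1 and 3 and Hmga2 replicate 2 and 31 of them immunoglobulin genes, which points to a structure of the samples. For lists, 4 of the 10 splits called at least 12, the labelled one among them, and the highest other split called 16.

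Hmga2 was no higher in the libraries labelled Hmga2. Low depth does not account for a missing 2-fold rise, since the upper bound of the 95% interval was 0.58. An exchange of labels between the groups stays open at a lower bound of -1.08, just past a 2-fold excess in the vector libraries. Reads of the introduced sequence may not have been counted for the mouse gene; Igf2bp2, at 0.39 with a standard error of 0.33, does not decide this. Loss of transduced cells over the 32 weeks was not tested.

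Immunoglobulin transcripts were high in vector replicates 1 and 3 and Hmga2 replicate 2 and low in the others. Plasma cell RNA could be a source, though the sort for c-Kit and Sca-1 should remove such cells. The median of 19 plasma cell genes between these libraries was 0.11 with a standard error of 0.10. It lay under the bound of 0.2 set beforehand but not by more than that error. Standard errors of list medians in this section come from the spread over genes, taken as independent. They do not cover the spread between libraries. In the low libraries 12 of the 19 genes were above 10 CPM, where a small share would be hidden. Among the other 7, whose limit of 10 CPM was set afterwards, the median was 1.07 with a standard error of 0.67. Of all 19, 14 were higher in the high libraries, and 5 had every high library above every low one. Jchain, Mzb1 and Cd79a, of the B cell and plasma cell list, were called higher there by edgeR, with log2 fold changes of 4.18, 3.93 and 4.15. The libraries were parted by Igha itself, so these calls are not independent of that choice. A difference between female and male cells was also considered. Vector replicate 2 had Xist at 547 CPM, above the 449 CPM of the lowest of the high libraries. By the first bound this argued against such a difference there. In a condition added afterwards, its Y-linked genes were at 21.4 CPM against at most 6.73 CPM in the high libraries. Of these genes, Ddx3y and Eif2s3y were at 4.5 and 7.15 CPM in vector replicate 2, against at most 0.41 and 0.567 CPM in the high libraries. Y-linked transcripts were thus present in vector replicate 2, and a share of male cells stays open. Hmga2 replicates 1 and 3 held transcripts of male cells, with Y-linked genes of at least 129 CPM, and replicate 3 also had Xist at 168 CPM. Whether this accounts for their low immunoglobulin level stays open. Cell sex thus partly followed the labels, and the 2 cannot be told apart in the labelled comparison. No other explanation was tested.

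A group of 12 neural and glial genes picked after their values were seen was higher in the vector libraries, most in replicates 1 and 2, with Mobp at 38.7, 46.7 and 4.98 CPM against 0.876, 4.68 and 0.758 CPM. Their median was -3.16 with and without immunoglobulin genes, which moved no fold change by over 0.03, so normalization was not put to a test. RNA of neural tissue or of another library may be a source. Of 18 neural genes not examined before, 13 were lower and 5 higher, with a median of -0.22 and a standard error over genes of 0.20. Camera gave adjusted p = 0.00501 with the preset correlation and adjusted p = 0.198 with an estimated correlation. The median lay past the bound of -0.5, set beforehand to argue against this source, by more than that error, which leaves out the spread between libraries. By the limit added afterwards, 6 of the 18 genes were above 10 CPM in the libraries labelled Hmga2, where a small share would be hidden. The other 12, with a median of -0.36 and a standard error over genes of 0.29, did not pass the bound by that error. The origin is therefore left open, although the sort should remove neural cells. Of abundant brain transcripts, Mbp was at 266, 312 and 108 CPM in the vector libraries and 118, 133 and 107 CPM in the others, and a biological difference between the labelled groups stays open, untested.

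Asns, which makes asparagine and is a target of the stress-response factor ATF4, was lower in the libraries labelled Hmga2 (log2 fold change -1.11), as was Atf4 itself (-0.39), though over all genes neither passed in edgeR (adjusted p = 0.855 for each) and both did in DESeq2 (adjusted p = 0.000216 and adjusted p = 0.0138). A lower amino acid response programme may be a candidate explanation for both. It was also considered for the metallothionein genes, which no test here covered. Of 31 further ATF4 targets, not examined before, 28 were lower, with a median of -0.18. A prediction for these 31 was written before their values were examined, but after Atf4, Asns and other targets had been seen to be lower. The 31 targets met it (adjusted p = 5.48e-08 with the preset correlation, adjusted p = 0.0914 with an estimated correlation). They are still read as undecided, by a comparison added afterwards. Another split of the libraries reached a median of 0.17, and 6 of the 10 splits passed the same preset test, with the smallest p in the labelled split. Unadjusted, camera gave p = 3.29e-08 with the preset and p = 0.0731 with an estimated correlation. The plasma cell, neural and ATF4 lists were adjusted together with the neural and ATF4 genes picked after their values were seen. Including those picked genes can lower the adjusted p-values of the other lists.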
